A study of Bacillus subtilis with 2 samples.

How the data were processed

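The 2 arrays were scanned at 635 nm for Cy5 (sample DNA) and 532 nm for Cy3 (1N reference DNA) and quantified by the authors with GenePix Pro 3.0.6.90 (GenePix Results format 1.4), per the file headers. The intensity columns used are the deposited mean brightness of each spot minus the median of its local background. The deposited log2 ratio columns were made by the authors, per the file headers, by scaling each array's channels to the same total signal; their signal is the spot mean times its pixel number with no background subtraction, as tested on the values. The authors also marked spots of low intensity, those with under 80% of pixels above background, and ran 3 rounds of outlier marking, per the file headers. The deposited series table equals the second, filtered log2 ratio column of the array files to within 5e-10 at 0 min (3953 spots) and to within rounding at 60 min (3960 spots, r = 1.00); its medians are -0.05 and -0.08, its direction is Cy5 over Cy3, and it is not centred. Growth, xylose addition and the making of the reference DNA are given per the labels.

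For the main values, log2 of Cy5 over Cy3 was computed for each spot and centred on the array's median, with no loess or quantile step, since most probes carry signal and regions may truly shift. Control spots of E. coli DNA (70), lacZ and gfp spots (3), removed probes (5) and gene spots marked by the scanner software or of low intensity in both channels (166 at 0 min, 160 at 60 min) were left out. Spots of a gene were averaged. Median local backgrounds were 214 and 200 in Cy5 and 258 and 240 in Cy3. The number of arrays, 1 per time point, limits the precision.

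The files name no genome build, so positions are ranks in the gene order of the reference assembly ASM904v1 (4536 entries), used only for which genes neighbour each other, and given in percent of that order clockwise from dnaA. Of 4053 gene names on the array, 2995 matched a symbol of that table, and 2841 of the 3851 genes with values in both arrays (73.8%) were placed. The table lists no older names, so the other 1010 genes entered only results that need no position.

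Origin and terminus were the break points of a continuous straight-line fit with 2 arms on the circular chromosome to the mean of both arrays, on a grid of 20 entries. The origin-to-terminus ratio used windows of 5% on either side, and slopes were least squares fits per arm. The 95% intervals come from 2000 bootstrap resamples of blocks of 50 neighbouring genes. The size rule was a difference of at least 1 on the log2 scale. Genes apart from their neighbours were at least 1 from a running median of 51 genes, on the same side in both arrays. For lists, the median difference was ranked among 10000 random lists of the same size, matched on mean signal in 10 bins, and, for neighbouring genes, among all 2841 runs of as many genes. Percentiles describe these arrays only.

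The lists were genes around oriC and dnaA-dnaN, replication proteins, xylose genes, arabinose genes, SP-beta, PBSX, the skin element, ICEBs1, ribosomal protein genes, the LexA regulon, and flagella and chemotaxis. Named genes were dnaA, dnaN, yabA, spoIIIJ, dnaB, rtp, amyE, thrC, lacA, xylA, xylR and araA; the 5 largest differences either way and the 5 highest and 5 lowest genes against their neighbours, among genes with signal above the lowest 25%; and landmarks at the fitted origin and terminus. Other genes, such as those of a list or a segment, were named after their values were seen. The design, lists, naming rule and alternatives were set before the data were examined.

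Segments were added after seeing the data: runs of at least 11 neighbouring genes whose running median of the difference, over 11 genes, passed 0.35 in size, compared with 25 flanking genes on each side. The procedure was tested on simulated data for 60 min minus 0 min with 2841 genes. A segment of doubled dosage was found in 20 of 20 runs. On simulated data without that segment, a set window change of 0.18 came back as 0.19 (SD 0.01), with windows at the set places. On such data the fitted origin lay within 0.882% and the terminus within 1.76% of the set places in 5 runs. How a segment in the origin window moves these values was not simulated. The size rule passed 100% of genes set to differ by 1.5 and 14.2% of genes set to differ by 1 on top of a simulated change of gradient.

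Alternatives were normexp background correction (offset 50), no background subtraction, the authors' log2 ratios, the series table, leaving out the lowest 25% of signals, keeping marked spots, the median of spots, origin and terminus at dnaA and rtp or fitted per array, leaving out mobile elements, windows of 2% and 10%, fitted lines, Theil-Sen slopes, a size rule of 0.5, a running median of 101 genes, differences with the running median taken off, and, added later, leaving out the segments. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.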

Results

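Genomic DNA of Bacillus subtilis strain AIG278 was profiled on 2-colour gene arrays. AIG278 is an oriC-null strain: the native origin is disabled and the chromosome replicates from oriN, a plasmid origin placed in it at a site that the labels do not give. Cells grew asynchronously in defined minimal medium with arabinose, and xylose was added at 0 min to overexpress dnaN, the gene of the sliding clamp of DNA polymerase. DNA taken at 0 min and at 60 min was labelled with Cy5, and each was hybridised with Cy3-labelled 1N reference DNA from cells arrested through dnaB-ts for 50 min at 42 C. In a replicating population genes near the origin are present in more copies than genes near the terminus, so the log2 ratio of sample to reference falls along each arm. There was 1 array per time point and no replicate. The intervals given therefore cover the scatter between probes within these arrays and not the variation between cultures, and no p-value was computed.

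Both arrays carried 4192 spots, of which 3948 at 0 min and 3954 at 60 min were used, and 3851 genes had a value in both. The median background-subtracted Cy5 signal of these spots was 7958.5 at 0 min and 6727.5 at 60 min, and the median Cy3 signal was 8536.5 and 7803.5. The E. coli control spots had median Cy5 signals of 48.5 and 31. Genes spotted more than once differed between their spots by an SD of 0.19 on the log2 scale at 0 min (48 genes) and 0.22 at 60 min (49 genes). The difference between the arrays had an SD of 0.08 between spots of the same gene (45 genes).

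The first question was how gene dosage ran along the chromosome at each time point. Outside the 2 segments described further on, the profile at both times was highest close to dnaA and lowest close to rtp, the gene of the replication terminator protein. The 2-arm fit placed the terminus at 45.9% of the gene order clockwise from dnaA, among yoaI, yoaH and pelB, next to rtp at 45.5%. The fitted origin lay at 3.09%, among rpsL, rpsG and rpoC, inside the segment from ctsR to kbaA, which differed between the arrays. Without the segments, the fitted origin lay at 1.32%, among purR, spoVG and veg. These are places of best fit, and the site of the working origin was not known. Genes within 2% of the gene order of dnaA, outside the segments, had a median log2 ratio of 0.43 at 0 min (SD 0.28 between genes) and 0.61 at 60 min (SD 0.30). Between 2% and 4% the medians were 0.21 and 0.32 (67 genes, 63 of them on the left side of dnaA), and between 40% and 50% they were -0.20 and -0.26 (590 genes).

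The main comparison asked whether this gradient differed before and after dnaN overexpression. Over all genes, the origin-to-terminus ratio, the median log2 ratio within 5% of the gene order of the origin minus that within 5% of the terminus, was 0.66 at 0 min (95% interval 0.49 to 1.41; 1.58-fold) and 0.80 at 60 min (0.67 to 0.89; 1.74-fold). The change was 0.14, with an interval of -0.56 to 0.23 that included 0. The origin window held the segment around the ribosomal protein genes, which was higher at 0 min. With both segments left out, a choice made after seeing the data, the ratio was 0.56 at 0 min (0.40 to 0.63; 1.47-fold) and 0.77 at 60 min (0.61 to 0.84; 1.70-fold), and the change was 0.21 (0.16 to 0.25; 1.16-fold). Origin and terminus were kept at the places fitted to all genes. The origin window was therefore still centred inside the left-out segment and held 203 genes. With a window of 2% on all genes, most of them in the segment, the change was -0.56, so its direction over all genes depended on the window.

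The same question was put to each arm. On the right arm, clockwise of the origin, the slope over all genes was -0.18 log2 units per 10% of the gene order at 0 min (-0.21 to -0.12) and -0.18 at 60 min (-0.20 to -0.16), a change of -0.0035 (-0.047 to 0.022). On the left arm the slope was -0.13 at 0 min (-0.15 to -0.096) and -0.15 at 60 min (-0.17 to -0.13), a change of -0.021 (-0.043 to -0.0085). Without the segments the right arm went from -0.13 to -0.18, a change of -0.043 (-0.049 to -0.034), and the left arm from -0.11 to -0.15, a change of -0.039 (-0.047 to -0.031). These slopes kept the origin and terminus fitted to all genes, so genes between dnaA and that origin counted to the left arm. The median difference between the arrays was 0.17 within 2% of dnaA, 0.05 between 10% and 15%, -0.01 between 20% and 30% and -0.06 between 40% and 50%.

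**Figure D1:**
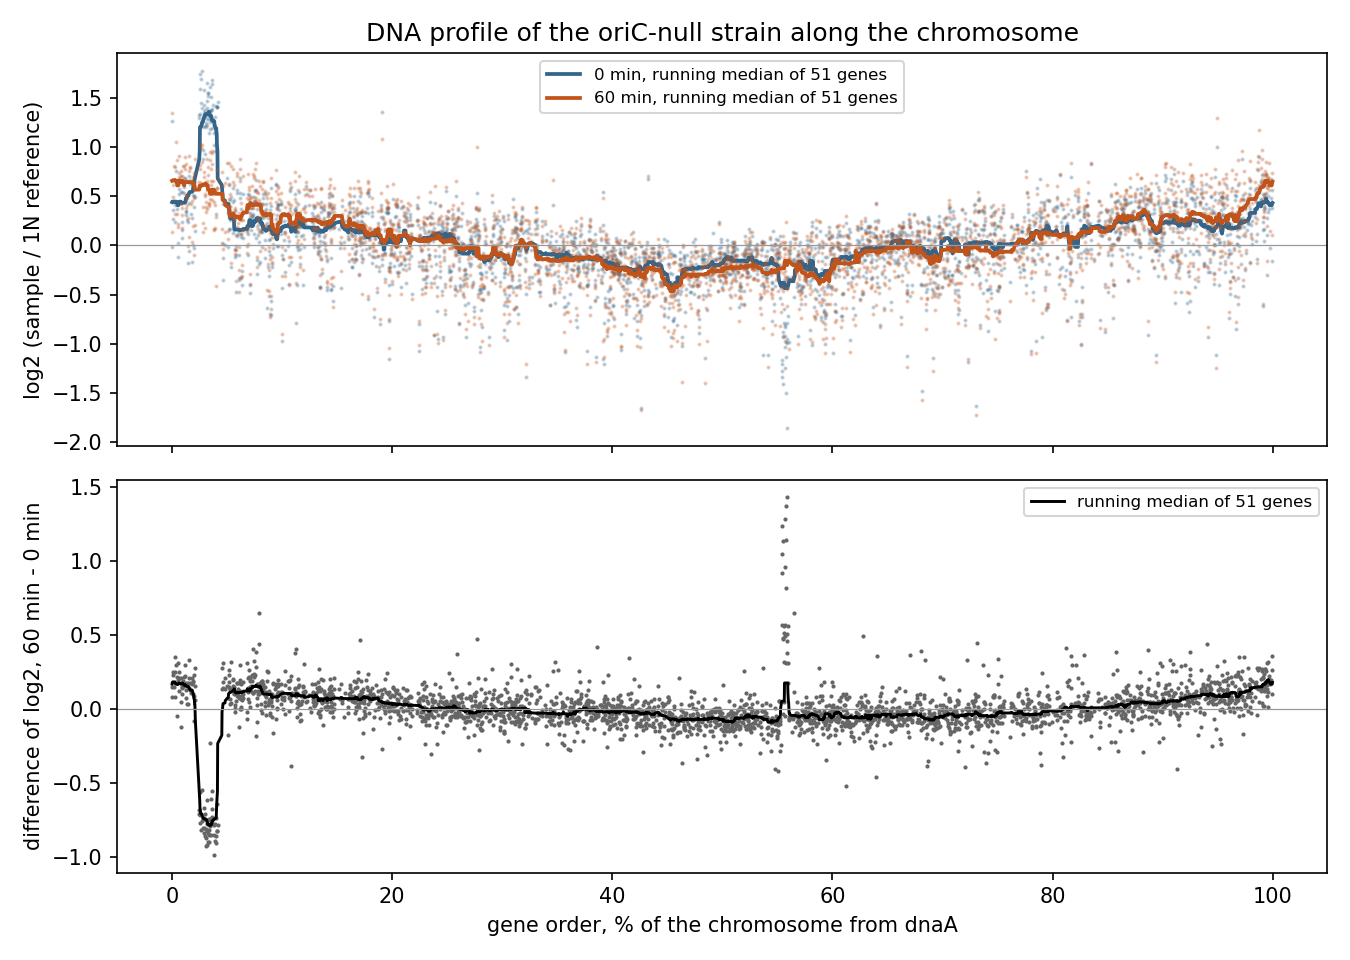
Log2 ratio of sample to 1N reference (top) and the difference between the arrays, 60 min minus 0 min (bottom), against gene order in percent of the chromosome clockwise from dnaA, for 2841 genes. Points are genes and lines are running medians over 51 genes; outside the segments both profiles fall from dnaA towards 45.9%, and the difference leaves the smooth trend at the segments from ctsR to kbaA and from mgsA to ndk.

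Across genes the profiles at 0 min and 60 min had a Pearson r of 0.904 and a Spearman rho of 0.949 (3851 genes, which are not independent replicates). After a running median over 51 neighbouring genes was taken off each array, r was 0.920 and rho 0.912 (2841 genes), so the position of a gene above or below its neighbours was largely shared by both arrays.

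The gene-by-gene comparison asked which genes differed between 0 min and 60 min, with the gradient left in. A total of 9 genes were higher at 60 min by at least 1 on the log2 scale, and 0 were lower by as much. With the running median taken off, over placed genes only, 5 were higher and 0 lower. Under normexp background correction 12 genes were higher and 24 lower, tufA (-1.14), ybaE (-1.15) and ybaJ (-1.07) among the lower, and with marked spots kept 13 were higher and 5 lower. The 5 largest were ypjG, 1.53 higher (2.89-fold), aroB, a dehydroquinate synthase gene of aromatic amino acid synthesis, 1.43 higher (2.69-fold), trpF of the tryptophan operon, 1.37 higher (2.59-fold), spoIIIJ, a membrane protein insertase gene next to oriC, 1.31 higher (2.47-fold), and hisC, an aminotransferase gene, 1.28 higher (2.43-fold). The other genes higher by at least 1 were ypjC, trpE, qcrB and ypjD. Each of the 5 largest had 1 spot in use at 0 min, so its own spread between spots is not known. Among genes with signals above the lowest 25%, the 5 largest differences in the other direction were those of tufA (elongation factor Tu), which was at 1.29 at 0 min and 0.37 at 60 min, ybaJ, rplB, ybaE and rpoC, an RNA polymerase subunit gene. Their differences were -0.92, -0.90, -0.90, -0.88 and -0.87. At a limit of 0.5, 20 genes were higher at 60 min and 71 were lower.

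Most of the genes with large differences lay in 2 segments, which were defined after the data were seen. The first ran from ctsR to kbaA, 57 measured and placed genes that include rpoB, rpoC, fusA, tufA and 30 ribosomal protein genes. Its median log2 ratio was 1.36 at 0 min (SD 0.24 between genes) and 0.59 at 60 min (SD 0.27), while the 50 flanking genes had medians of 0.34 and 0.48. All 57 genes were lower at 60 min, from rpsK at -0.99 to rplE at -0.23, with an SD of the difference of 0.12. Set against the flanks, the segment was 1.91-fold higher at 0 min than at 60 min. The difference broke off between lysS (0.15) and ctsR on the left and between kbaA and ybaR (0.27) on the right. In the reference gene order, 6 rRNA genes lie between lysS and ctsR and 9 between kbaA and ybaR.

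The second segment ran from mgsA to ndk and held 26 genes, among them the tryptophan operon (trpE, trpD, trpC, trpF, trpB, trpA), the aromatic pathway genes aroB, aroF, aroH and tyrA, hisC, and the cytochrome bc complex genes qcrA, qcrB and qcrC. Its median log2 ratio was -0.94 at 0 min and -0.25 at 60 min, against -0.12 and -0.16 in the flanks. A total of 24 of the 26 genes were higher at 60 min, but unevenly, from -0.05 for aroA to 1.43 for aroB (SD 0.43, against 0.17 in the flanks). Differences of qcrC, qcrA and aroA lay within 2 SD of the flanks. The gene after the segment, hepT, which counts among the flanking genes, was 0.56 higher at 60 min, so the right edge was not sharp. No rRNA gene lies at its edges, and ypjG has no place in the gene order used.

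**Figure D2:**
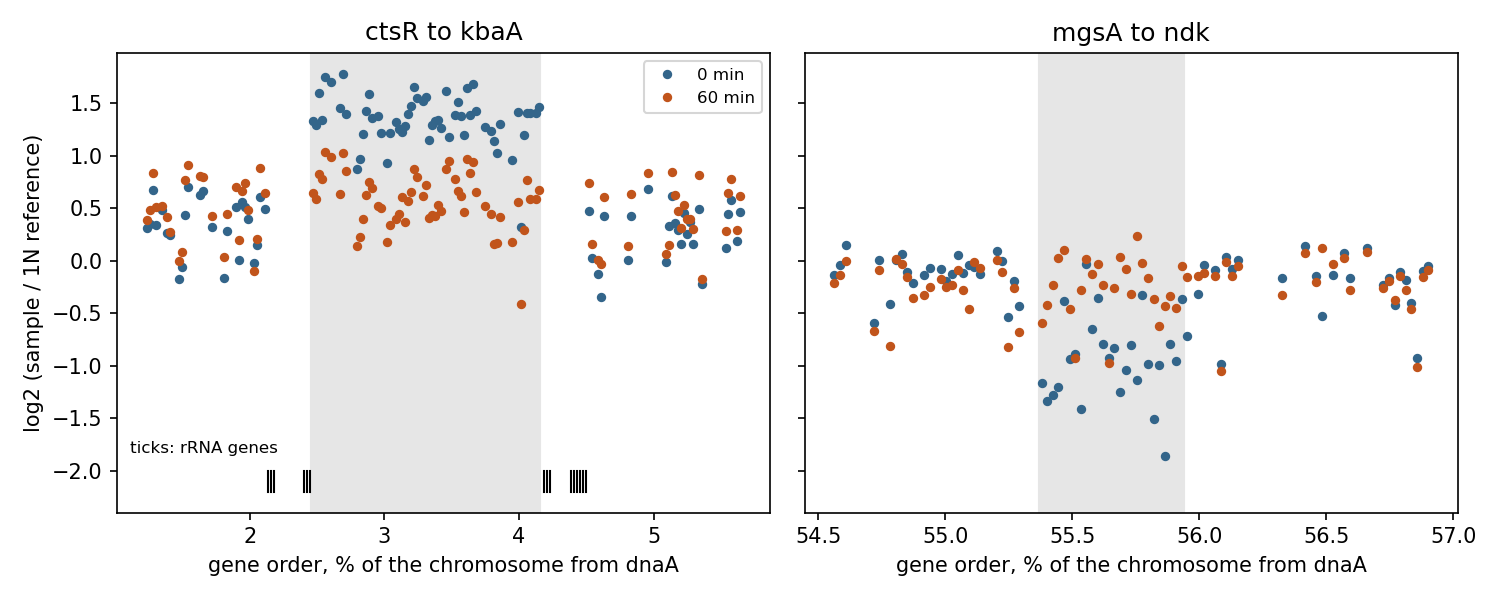
Log2 ratio of sample to 1N reference of each gene at 0 min and 60 min, against gene order in percent from dnaA, in the segments from ctsR to kbaA (left) and from mgsA to ndk (right) and 25 genes on either side. Grey marks the segment and short vertical lines mark rRNA genes; the left segment is shifted evenly, by a median of -0.78, and the right segment unevenly, by a median of 0.54 (60 min minus 0 min).

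The genes tied to the strain and the treatment differed little apart from spoIIIJ. The log2 ratio of dnaN, the overexpressed gene, was 1.27 at 0 min and 1.35 at 60 min, which is 1.77-fold and 1.62-fold above the running median of its neighbours. Its neighbour dnaA, the replication initiator gene, was at -0.01 and 0.14, which is -0.45 and -0.52 against the same running median. The gene of the initiation regulator YabA was at 0.76 and 0.97, spoIIIJ at -0.35 and 0.96, dnaB, a helicase loading gene, at 0.08 and 0.04, and rtp at -0.44 and -0.63. Of the sugar genes, xylR, the xylose repressor gene, was at 0.67 and 0.71 (1.82-fold and 1.92-fold above its neighbours), xylA at -0.50 and -0.52, and araA at 0.22 and 0.29. The loci thrC (0.01 and 0.02) and lacA (0.26 and 0.27), common sites of insertion, hardly differed in the main values. Under normexp the differences of thrC, lacA, xylR and araA were -0.03, -0.20, -0.10 and -0.02, on the other side of 0. Those of thrC and lacA also lay there with the log2 ratios of the authors, at -0.02 each. The spot of amyE was excluded for its quality, so it has no value.

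Among the lists of genes fixed in advance, 6 of 11 had a median difference outside the central 95% of random lists of the same size and signal. With the running median taken off, which also leaves out genes without a place in the order, 2 lists lay outside. These were SP-beta (median near 0, percentile 98.6) and replication proteins (median -0.03, percentile 2.11). Genes around oriC and dnaA-dnaN had a median of 0.39 at 0 min and 0.68 at 60 min, with 15 of 16 higher at 60 min, among them soj by 0.29 and gyrB by 0.23; the median difference of 0.19 stood at percentile 100 of random lists and percentile 98.2 of runs of 16 neighbouring genes, and the median was 0.01 with the running median taken off. Ribosomal protein genes had a median difference of -0.73 (45 of 49 lower, percentile 0), made up of -0.79 for the 30 inside the segment and -0.05 for 16 outside it. Without a place in the order were rplN (-0.77) and rpsN (-0.62), which differed much as the segment did, and rpmE (-0.02). With the running median taken off, the list had a median of -0.04. For the genes inside the segment, that running median was drawn largely from the segment itself. The mobile element ICEBs1 was higher at 60 min by a median of 0.11 (19 of 22 genes, percentile 100; percentile 89.3 of runs), and the prophage SP-beta, near the terminus, had a median of -0.07 (131 of 157 lower, percentile 0; percentile 4.19 of runs). With that median taken off, SP-beta and ICEBs1 had medians of 0.00054 (140 placed genes) and -0.012 (11 placed genes), on the other side of 0 from the -0.07 and 0.07 of the same placed genes before.

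Arabinose genes had a median difference of -0.05 (7 of 11 lower, percentile 1.43), with araL at -0.13 and araR at 0.12, and a median of -0.01 with the running median taken off. Under normexp their median was -0.10, and with the log2 ratios of the authors it was -0.07. Genes of the LexA regulon, the DNA damage response, had a median of -0.07 (9 of 11 lower, percentile 2.24), with uvrC at -0.23 and recA at -0.0036. With the lowest 25% of signals left out, the median was -0.02 over 7 genes (percentile 22.7), and under normexp it stood at percentile 13.7. The 9 placed genes also had a median of -0.02, against -0.14 for yneA and yneB, which had no place. Replication proteins had a median of 0.03 (11 of 21 higher, percentile 58.3), from -0.42 for dnaD to 0.23 for gyrB. Xylose genes had a median of -0.01 (4 of 5 lower, percentile 43.0), the prophage PBSX -0.01 (15 of 28 lower, percentile 30.7; percentile 51.7 of runs), the skin element -0.04 (35 of 46 lower, percentile 5.80; percentile 26.8 of runs; percentile 0.950 under normexp and 1.03 with the log2 ratios of the authors), and flagella and chemotaxis genes 0.0039 (19 of 36 higher, percentile 63.7).

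The last comparison asked which genes stood apart from their neighbours at both time points. By at least 1 on the log2 scale in each array, 1 gene was higher, yfmG, and 21 were lower, of 2841 genes placed. Among genes with signals above the lowest 25%, the 5 highest against their neighbours in the mean of both arrays were yxjC (0.93), xylR (0.90), dnaN (0.76), yufS (0.70) and fhuB (0.70), an iron uptake gene. Under normexp these were 0.69, 1.33, 1.11, 1.11 and 0.41, in another order. The 5 lowest were scoB (-1.40), dppC (-1.28) of dipeptide transport, yfkQ (-1.23), gabD (-1.18) and opuBD (-1.12) of choline transport. The gene yxjC, highest under this rule, lies close to scoB, the lowest under it. With the lowest 25% of signals left out, 8 genes passed this rule, all lower, and under normexp 102 passed it, 4 higher and 98 lower. The sample was in Cy5 on both arrays, so these offsets hold any dye effect of a probe. The labels name AIG278 for the reference DNA as well, which leaves unsettled whether sample and reference differ in copy number at genes such as dnaN and xylR.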

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

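Over all alternatives, 132 recomputed main results kept their value within its interval, or their count within 1.5 times, and 18 did not. The alternatives are not independent. The median of spots repeated the main values, and no background subtraction and the authors' log2 ratios gave the same ratios and slopes as each other. A 2% window change of -0.56 and a normexp right-arm change of 0.0066 count as kept, since both lie within intervals that include 0. The change in origin-to-terminus ratio ranged from -0.56 to 0.22 over 14 alternatives and was negative only with the 2% window, with most of its genes in the segment from ctsR to kbaA. The right-arm slope change ranged from -0.043 to 0.0066 over 12. Normexp gave a ratio of 1.08 at 60 min, right-arm slopes of -0.22 (0 min) and -0.21 (60 min), left-arm slopes of -0.17 and -0.20, 36 genes past the size rule and 102 apart from their neighbours. The 2% window gave ratios of 1.49 and 0.93 and the 10% window 0.48 and 0.63 at 0 and 60 min. A limit of 0.5 gave 91 genes past the size rule and 197 apart from neighbours. Keeping marked spots gave 18 genes past the size rule, the added choice of leaving out both segments gave 2, and leaving out dim genes gave 8 apart from neighbours. The 2 were ypjG and spoIIIJ, which have no place in the order and so could not be left out with a segment. With the running median taken off, over placed genes only (without ypjG and spoIIIJ), 5 genes passed the size rule, 2 lists stood outside random lists, and the medians of SP-beta and ICEBs1 reversed to 0.00054 and -0.012, from -0.07 and 0.07 in the same placed genes. For SP-beta this follows largely from the method, since that running median was drawn largely from its own genes. Otherwise the cause was not tested. No paired analysis was possible because there was 1 array per time point and the labels carry no replicate numbers, and no array could be left out. Median Cy5 signals of 7958.5 and 6727.5 stood over local backgrounds of 214 and 200, yet normexp moved brighter genes too, such as xylR from 0.90 to 1.33.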

Other observations

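Several gene groups outside the main comparison were also read from the profiles. On the left side of dnaA both arrays showed a drop in the log2 ratio. The median fell from 0.44 within 2% to 0.21 between 2% and 4% (63 genes) at 0 min, and from 0.60 to 0.32 at 60 min. It was 0.17 and 0.25 between 4% and 6%, 0.26 and 0.33 between 6% and 8%, and 0.23 and 0.30 between 8% and 10%. Being shared by both arrays, the drop may also hold effects of the probes, the dye or the reference DNA. On the right side the segment from ctsR to kbaA covers the stretch between 2% and 4%, where only 4 genes remain with it left out. The right-side medians were 0.43 at 0 min and 0.64 at 60 min within 2%, and 0.26 and 0.31 between 4% and 6%. They fell as well, but where between these places was not examined. Near oriC, rnpA stood at -0.59 against its neighbours at 0 min and -0.54 at 60 min, below them as dnaA was, while rpmH was at 0.13 and 0.02 against them. Apart from spoIIIJ, the other 15 genes of this neighbourhood differed between the arrays by -0.09 (spo0J) to 0.36 (jag).

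The tests in this part were chosen after the results were seen, except that of adjacent spots, which was chosen after the pattern but before its own value. The first pattern is the segment from ctsR to kbaA, 1.91-fold higher at 0 min. The reference channel carried 31.3% of the summed shifts, so a difference in reference DNA is not the whole source, and the 372 spots next to those of the segment on the slide had a median difference of 0.0104 (SD 0.15), against -0.78 in the segment, which argues against a fault of position on the slide. Only 1 of 2841 runs of as many genes has rRNA genes in both end gaps, and that run is the segment itself. The run length was taken from the segment, so stretches of other lengths between rRNA genes were not counted. A candidate explanation, not tested further, is a copy-number change by recombination between the rRNA operons, present at 0 min. Whether the DNA of both arrays came from cells of different genotype, or the labels of the arrays are exchanged, cannot be told apart from a change within the culture with 1 array per time point, and an exchange would turn every direction from 0 min to 60 min. The segment stood out from its flanks at 0 min (1.02, against 0.11 at 60 min), when xylose was added. By the labels the raised dosage was therefore seen before dnaN overexpression. Why it was not seen at 60 min was not tested, and overexpression, further growth, a different genotype and exchanged labels all stay open.

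The second pattern is the segment from mgsA to ndk, lower at 0 min. The reference channel carried 12.6% of the summed shifts. The SD of the difference was 2.51 times that of the flanks, which argues against an equal change in the copies of every gene, as a mixture of cells with and without the segment would give, and 26 of 26 genes had Cy5 signals at 0 min above the highest E. coli spot (median 4589.5 against 1701), which argues against its absence from all cells. Sequence in the 0 min DNA that differs from the probes may also give an uneven loss with little-changed genes between, and 3 genes (qcrC, qcrA, aroA) lay within 2 SD of the flanks, but without probe sequences this stays open. As with spoIIIJ, the difference lay mainly in the sample channel. The log2 Cy5 signal of spoIIIJ was 1.13 higher at 60 min, while its Cy3 signal differed by -0.19. The departure of the segment from its flanks was again at 0 min (-0.82, against -0.09 at 60 min), by the labels before dnaN overexpression. For this segment and spoIIIJ too, cells of different genotype or exchanged labels cannot be told apart from a change within the culture.

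The third pattern is the steeper gradient at 60 min. Over all genes the change in the origin-to-terminus ratio was 0.14, with an interval of -0.56 to 0.23. The slope change over all genes was -0.021 (-0.043 to -0.0085) on the left arm and -0.0035 (-0.047 to 0.022) on the right. The scatter of genes around their running median was 1.06 times as large at 60 min (1.05 to 1.08), less than the 1.38 times of the origin-to-terminus value without the segments, so a common stretch of all log2 ratios is not the whole source. The segment from ctsR to kbaA lay in the origin window and was lower at 60 min, so it worked against a rise and was not its source. Leaving out the 2 segments was therefore set to raise the change, from 0.14 to 0.21, and is no separate support for it. Variation between cultures or arrays, or in genotype, cannot be told apart from an effect of dnaN overexpression or of 60 min of further growth. There was 1 array per time point and no array of uninduced cells at 60 min.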
